A study of Gallus gallus with 2 samples.

How the data were processed

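Total RNA of intestinal intraepithelial lymphocytes from anethol-fed and from non-treated control broilers, age day 14, was hybridised on 2 two-colour Agilent chicken arrays. Per the labels' protocols, RNA was extracted with Trizol and labelled with Cy3 and Cy5 by a 2-colour amplification kit with spike-in RNA. Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 10.7.3.1, both on 1 slide and at 1 scan time, so slide and scan are shared by both replicates and were not tested as batches. The deposited scanner files give, for each spot and channel, the mean brightness of the spot and the median brightness around it as intensity values on a linear scale, with no normalisation. Per the file headers they also hold processed intensity values, which the scanner software had background-subtracted, detrended over the slide and dye-normalised within the array. The scanner's log ratio in the deposited files is log10 of Cy5 over Cy3, and it was exactly 0 at 32.7% of probe spots in replicate 1 and 32.1% in replicate 2. The authors' series table holds log10 ratios as well. It equalled the scanner's log ratio in replicate 1 and the negative of it in replicate 2, to within 4.97e-06, so its scale is log10 and its direction anethol over control, and its column medians were 0 and 0. This fixes the direction of the ratios, which the dyes in the labels give in the same way.

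Each array held 43451 spots, of which 1417 were control spots and 42034 gene probes. Outlier flags marked 203 probe spots in replicate 1 and 477 in replicate 2. In limma 3.58.1 under R 4.3.3, the mean signals were corrected against the median local background by normexp with an offset of 50, and each array was normalised by loess with control spots at weight 0. The ratio of replicate 2 was multiplied by -1. Spots of 1 probe were averaged. Tested probes were those with no outlier flag that were well above background in at least 1 channel on both arrays, which left 19017. The spike-in transcripts, 10 in number, had an observed against expected slope of 1.09 in replicate 1 and 0.986 in replicate 2, with correlations of 0.953 and 0.993 in the file headers. Neither value shows a common offset. The Cy5 over Cy3 log2 ratio of all 10 was lower in replicate 2 than in replicate 1, as in 2.24 against 5.98 and -4.10 against -1.24. With the dyes exchanged, such a difference points towards the anethol channel on at least 1 array. Its cause was not tested. The offset of 50 draws the ratios of dim probes towards 0, so their log2 ratios understate the difference.

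Probes were named from the array's own annotation, brought up to date through the RefSeq gene table of the GRCg7b assembly. Of 42034 probes, 5193 were named by accession, 3650 by gene identifier, 888 by symbol and 303 by synonym, and 161 kept the file's name. The remaining 31839, mostly expressed sequence tags and clones, stayed without a gene name. Of the tested probes, 6665 carried a name, for 5990 genes. Coordinates are those of the array annotation on galGal2, and no genome sequence was used here. A gene was represented by its probe with the highest mean intensity.

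The main test was limma's lmFit and eBayes of the oriented log2 ratios against 0, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. It has 1 residual degree of freedom per probe and borrows 4.27 prior degrees of freedom from all probes. A count of probes at least 2-fold apart on both arrays was set beside it, with the same count in the dye direction. Gene lists were tested with camera at a preset correlation of 0.01 against all other named genes, with adjustment over the 21 lists that had at least 5 measured members. There were 22 lists: T cell, cytotoxic and NK cell, B cell and plasma cell, macrophage and dendritic cell, heterophil, enterocyte and epithelial cell, erythrocyte, thrombocyte, smooth muscle and stroma, proinflammatory cytokine and chemokine, anti-inflammatory and regulatory, toll-like receptor and NF-kappaB, interferon response, antigen presentation, xenobiotic and antioxidant response, heat shock and endoplasmic reticulum stress, cell cycle, tight junction and mucosal barrier, lipid metabolism and PPAR, apoptosis, ribosomal protein, and oxidative phosphorylation. As a description, the median of each list was ranked among 10000 random lists of the same size matched on mean intensity. Named genes were taken by rule: the 10 largest in each direction among named genes past the test with the same sign on both arrays, filled up to 10 by genes at least 2-fold in that direction on both arrays; up to 4 members of each list with the largest absolute mean among those with the same sign on both arrays; and 18 cytokine and marker genes whatever their values. The values of 2 genes taken by this rule are not reported, though the counts include them. The tests, lists, rule and alternatives were fixed before the data were examined. Chosen after values were seen were the alternative without exocrine pancreas genes, the difference of 0.1 up to which a correlation counts as the same, the limits used for probes raised on 1 array only, and all the patterns weighed at the end with their gene lists, whose bounds were written before the values of the unseen genes. A further condition, that a list's median must stand clear of the spread of its members before an explanation counts as ruled out, was added after those values were seen. A probe that was not well above background in the channel of one RNA on both arrays was given a bound, from channel intensities after loess and quantile normalisation of the mean intensities.

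The scripts were tested on simulated data for the comparison of anethol with control, with 19017 probes, spread drawn from the fitted prior and 200 probes changed by known folds. The limma test recovered 10% of the probes changed 2-fold and 92% of those changed 4-fold, and 98% of those changed 8-fold and 98% of those changed 16-fold. It called 7 of 18817 unchanged probes. The 2-fold criterion on both arrays recovered 32%, 98%, 100% and 100% of the changed probes, in the same order, and took in 26 unchanged probes. The simulated noise was independent and followed the variance model of the limma test itself, without a dependence on intensity. These counts therefore check the scripts and do not measure false calls in the data. Alternatives varied the background correction, the normalisation, the filter on dim probes, the source of the values, the variance model, the dye direction, the size threshold, the replicates, and the gene list test and its correlation.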

Results

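The series compared gene expression in intestinal intraepithelial lymphocytes, the lymphocytes that lie between the epithelial cells of the gut lining, from broiler chickens fed anethol and from non-treated control chickens. Anethol is the aromatic compound that gives anise and fennel oils their smell. The series title places the work in infection with Eimeria maxima and Eimeria tenella, the protozoan parasites of avian coccidiosis, but the sample labels give only the age, day 14, and do not say whether the sampled birds had been infected. Total RNA of an anethol-fed group and of a control group was hybridised together on each of 2 two-colour Agilent chicken arrays. Replicate 1 carried anethol RNA in Cy5 and control RNA in Cy3, and replicate 2 carried the dyes the other way round. The labels call both arrays biological replicates and also call the second a dye exchange of the first, so the spread between them may be partly or wholly technical. The limma p-values rest on the spread between these arrays only, moderated by 4.27 prior degrees of freedom from all probes against 1 residual. The camera p-values set each list against the other named genes at a preset correlation. They do not measure how a list would vary between replicates. Each array held 42034 spots with gene probes. In replicate 1, 47.2% of these were well above background in the anethol channel and 36.7% in the control channel. In replicate 2 the shares were 40.7% and 52.9%, so on each array the channel with more spots above background was Cy5. No spot was saturated. The number of arrays, 2, limits the precision of every value below. All ratios are log2 of anethol over control, with the SD over the 2 arrays.

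The question put to these arrays was which transcripts differed between the lymphocyte preparations of anethol-fed and control birds. Among named genes, the transcripts that fell furthest with anethol encode digestive enzymes that are textbook products of the exocrine pancreas. All 8 named genes that were lower past the test were of this kind or, for CPA5, a carboxypeptidase of the same family. This grouping was made after the values were seen. A further 7 lower probes past the test carry no gene name. CELA2A, a pancreatic elastase, fell to a log2 ratio of -5.14 ± 0.46 (SD, n = 2), which is 35.1-fold lower. AMY2A, an amylase, had a log2 ratio of -4.15 ± 0.21. The carboxypeptidases CPA1, CPB1 and CPA5 had ratios of -4.05 ± 0.37, -2.96 ± 0.27 and -1.93 ± 0.02. CEL, the bile salt-stimulated lipase, stood at -3.41 ± 0.27 and CTRC, chymotrypsin C, at -3.37 ± 0.02. Their adjusted p-values in limma ran from 0.00427 for CELA2A to 0.0392 for CPA5. Each passed in 3 or 4 of the 8 processing alternatives. The probes of CPA5 and CPA1 lie close together on chromosome 14 of the galGal2 build, from 14842644 to 14842703 and from 14847700 to 14847759. The CELA2A probe lies on chromosome 21 from 5278126 to 5278185, and the CEL probe on chromosome 17 from 3634191 to 3634250. Whether a probe lies in an exon or a UTR was not analysed here. With fewer than 10 named genes past the test in this direction, the list was filled by size: PNLIPRP1, a lipase-related pancreatic protein, at -4.13 ± 1.33 (adjusted p = 0.063) and PLA2G1B, the pancreatic phospholipase, at -2.10 ± 0.73 (adjusted p = 0.0774) missed the test but were at least 2-fold lower on both arrays.

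Only 3 named genes rose past the test. GDF2, a secreted ligand of the TGF-beta family also known as BMP9, had the highest value, 3.20 ± 0.05 (SD, n = 2), which is 9.19-fold higher at an adjusted p of 0.00758. ASS1, the argininosuccinate synthase of arginine synthesis, had a ratio of 2.12 ± 0.11 (adjusted p = 0.0369). MDK, the heparin-binding growth factor midkine, had a ratio of 2.04 ± 0.02 (adjusted p = 0.0376), and its control channel was well above background on 1 of the 2 arrays. A second MDK probe gave 1.36 ± 0.17 and missed the test at an adjusted p of 0.0729. GDF2 and ASS1 each passed in 3 of the 8 processing alternatives, 2 of which rest on the same scanner values, and MDK in 2 of the 7 where it was measured. All 3 also passed with an intensity trend and with robust moderation of the variance. When the probes of named exocrine pancreas genes were left out, an alternative chosen after seeing the data, only 1 higher probe passed. At most 1 of these 3 genes therefore kept its call there. Of all higher probes in the main limma test, GDF2 had the smallest adjusted p-value. The GDF2 probe lies on chromosome 6 from 17179642 to 17179701, and the ASS1 probe on chromosome 17 from 4955802 to 4955861. The 7 genes that filled this direction missed the test and differed more between the arrays. HBA1, an alpha globin, stood at 2.84 ± 1.66 (4.01 on replicate 1 and 1.66 on replicate 2; adjusted p = 0.119); its other probe was not above background in any channel. FZR1, an activator of the anaphase-promoting complex, stood at 2.37 ± 1.03, but its other probe at 0.26 ± 0.16. ATP2A1, the calcium pump of fast muscle, stood at 2.05 ± 1.16. The cytoskeletal linker MACF1 had 2.04 ± 0.32, with the control channel above background on 1 array, and 0.11 ± 0.02 with its other probe. ZZEF1 had 1.97 ± 0.69, the kinase gene STK11 1.96 ± 1.05 and the neuropeptide gene HCRT 1.96 ± 0.48. Adjusted p-values of these 7 genes were 0.0513 or more.

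**Figure D1:**
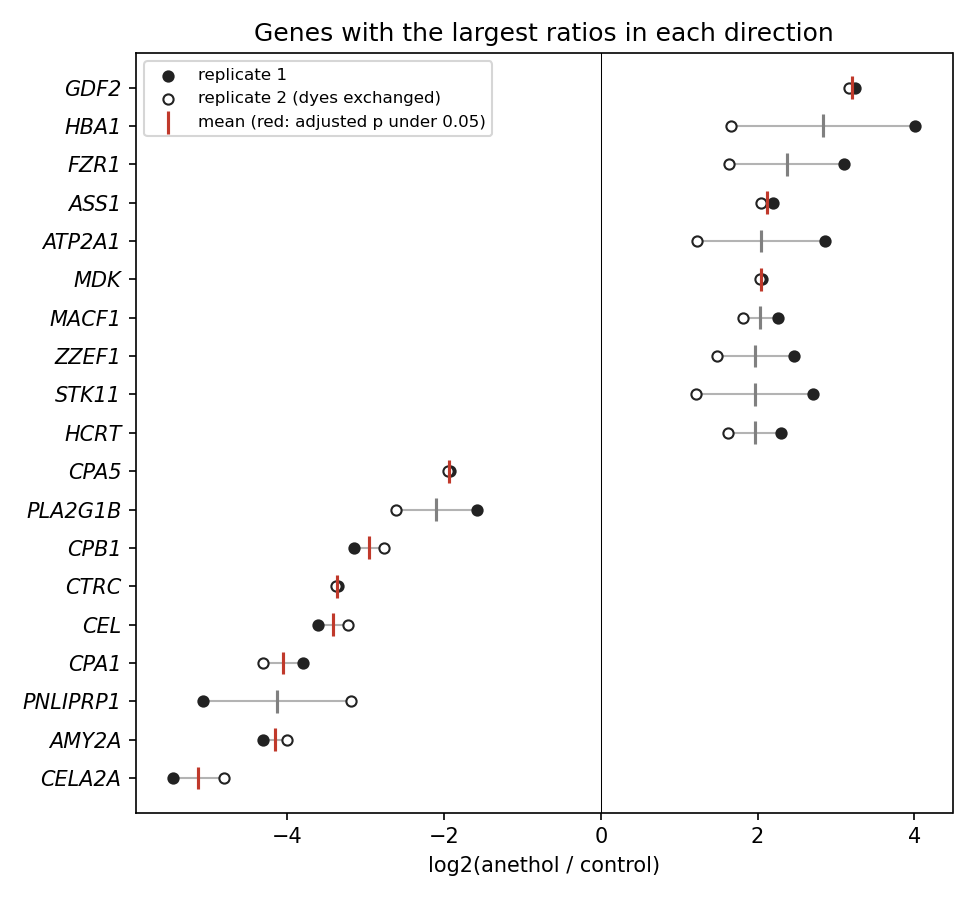
Log2 ratio of anethol over control for the reported genes with the largest ratios in each direction; filled circles are replicate 1, open circles replicate 2 with the dyes exchanged, and bars the mean, red where the limma adjusted p was under 0.05. The digestive enzyme genes lie between -5.14 and -1.93 in the mean, and GDF2, ASS1 and MDK are the red bars on the right.

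Over all 19017 tested probes, 28 passed an adjusted p of 0.05 in limma, 13 higher and 15 lower with anethol. Of these, 11 carried a gene name, 3 higher and 8 lower. At an unadjusted p under 0.05 there were 3224 probes, 2042 higher and 1182 lower, where 951 would fall by chance. The same test in the dye direction, whose mean holds no treatment effect, called 0 probes in limma and gave 44 at an unadjusted p under 0.05. With 2 arrays, any treatment difference enters the spread of that test. Its 44 lay below the 951 of chance, so it does not measure false calls among the 28. By size alone, 246 probes were at least 2-fold apart on both arrays in the same treatment direction, 205 higher and 41 lower, and 0 were in the same dye direction. Loess takes out much of the dye effect of each array: without it, after median centring, 1193 probes were in the same dye direction against 73 in the treatment direction. With loess kept, an offset of 16 in place of 50 gave 12 against 441. The scanner's processed signals, dye-normalised by its own software, gave 309 against 1191. Their ratios were wider, with SDs of 1.17 and 0.76 on replicates 1 and 2 against 0.58 and 0.38 in the main setting. The split between higher and lower also depended on the normalisation. After median centring without loess, 30 probes were at least 2-fold higher on both arrays and 43 lower, and 0 higher and 14 lower probes passed the test. Under this setting the tested probes had a median of 0.27 on replicate 1 and -0.82 on replicate 2. That shift makes a 2-fold rise on replicate 2 harder to reach than a fall. Values of genes and lists given below for this setting carry the same shift. The number past the test was set by the processing, from 0 with the scanner software's own processed signals to 1929 with a background offset of 16, and it was 5 when the probes of named exocrine pancreas genes were left out, an alternative chosen after seeing the data.

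Across the tested probes, the oriented log2 ratios of the arrays had a Pearson r of 0.55 and a Spearman rho of 0.478, and 64.8% of probes had the same sign on both. Probes are not independent replicates, so these are descriptions with no p-value. Replicate 1 had the wider ratios, with an SD of 0.58 against 0.38 for replicate 2. After median centring without loess the Pearson r was 0.0465.

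**Figure D2:**
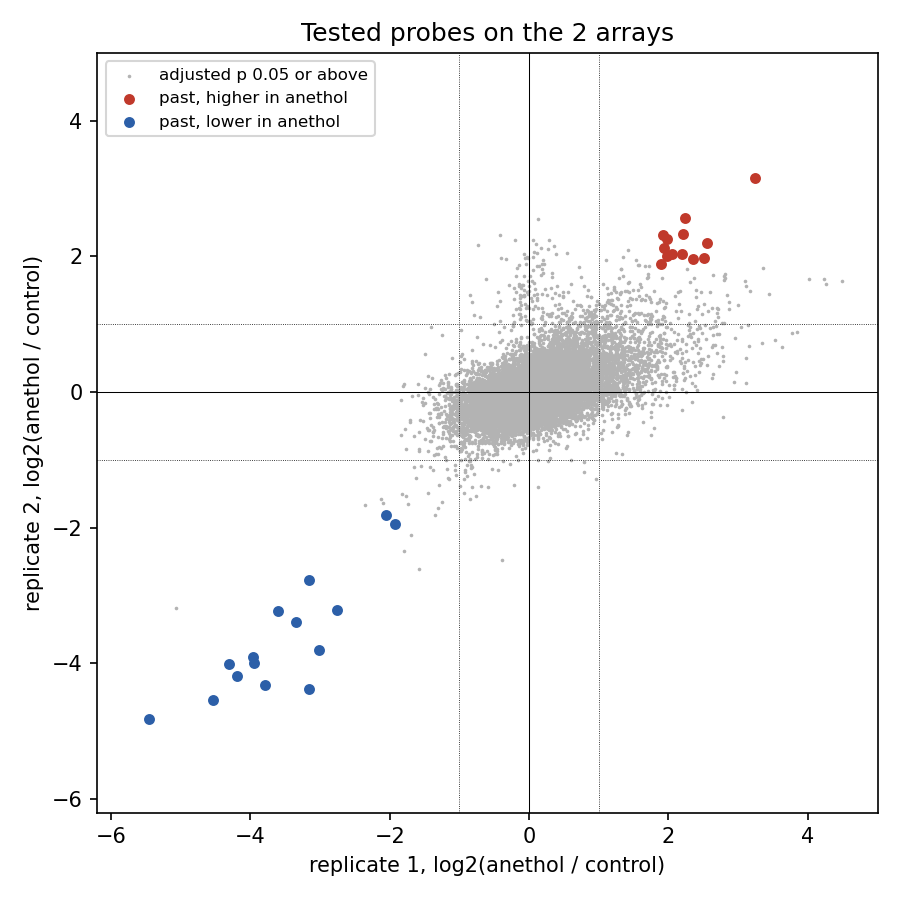
Each point is 1 of the 19017 tested probes, with the log2 ratio of anethol over control on replicate 1 (horizontal axis) and replicate 2 (vertical axis); dotted lines mark 2-fold. The 15 blue probes passed the limma test as lower and the 13 red ones as higher, and the Pearson r over all probes was 0.55.

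Of the 21 gene lists fixed beforehand that had 5 or more measured members, 3 passed an adjusted p of 0.05 in camera, cell cycle and heat shock as lower and erythrocyte as higher. Cell cycle genes fell as a group with anethol: the median log2 ratio of the 34 measured members was -0.21, with -0.27 on replicate 1 and -0.13 on replicate 2, and 24 members were negative on both arrays against 2 positive on both (adjusted p = 0.0291). The call was lost with an estimated correlation (adjusted p = 0.781 with an estimated correlation), an estimate that rests on 1 residual degree of freedom. No member passed alone, over all probes or adjusted over the list alone. The kinetochore gene NUF2 had -0.90 ± 0.11, the mitotic motor gene KIF11 -0.59 ± 0.53, the ribonucleotide reductase gene RRM2 -0.51 ± 0.45 and the survivin gene BIRC5 -0.49 ± 0.18. Heat shock and endoplasmic reticulum stress genes also fell as a group, with a median of -0.27 over 29 members, of which 16 were negative on both arrays and 4 positive on both (adjusted p = 0.0419, but adjusted p = 0.781 with an estimated correlation). None of them passed alone, also when adjusted over the list alone. Its largest values were those of the asparagine synthetase gene ASNS at -0.94 ± 0.21, CRELD2 at -0.87 ± 0.79, the co-chaperone gene DNAJB9 at -0.79 ± 0.41 and HSP90B1, the chaperone of the endoplasmic reticulum, at -0.60 ± 0.38. The cell cycle call was also lost under median centring and under the stricter filter on dim probes, and the heat shock call in 6 of the 9 alternatives of processing and probe choice. With fry in place of camera neither list passed (adjusted p = 0.367 and 0.422). The pancreatic enzyme genes moved the same way, so these arrays do not settle in which cells the lists fell.

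Red blood cell genes were higher with anethol as a group, which rested on the globins. The 6 measured members of the erythrocyte list had a median of 0.34 (0.41 on replicate 1 and 0.26 on replicate 2; adjusted p = 0.0419). Its call too was lost with an estimated correlation (adjusted p = 0.781 with an estimated correlation), and with fry (adjusted p = 0.367). HBA1 stood at 2.84 and the beta globin HBBA at 1.80 ± 0.46, and these 2 passed when adjusted over the list alone, while 0 members passed over all probes. The Rh-associated glycoprotein gene RHAG had 0.34 ± 0.07, with its control channel above background on 1 array, and the carbonic anhydrase gene CA2 had -0.34 ± 0.46. The call was lost without background subtraction (adjusted p = 0.0623) and without a filter on dim probes (adjusted p = 0.266), and the stricter filter left fewer than 5 members, too few to test.

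**Figure D3:**
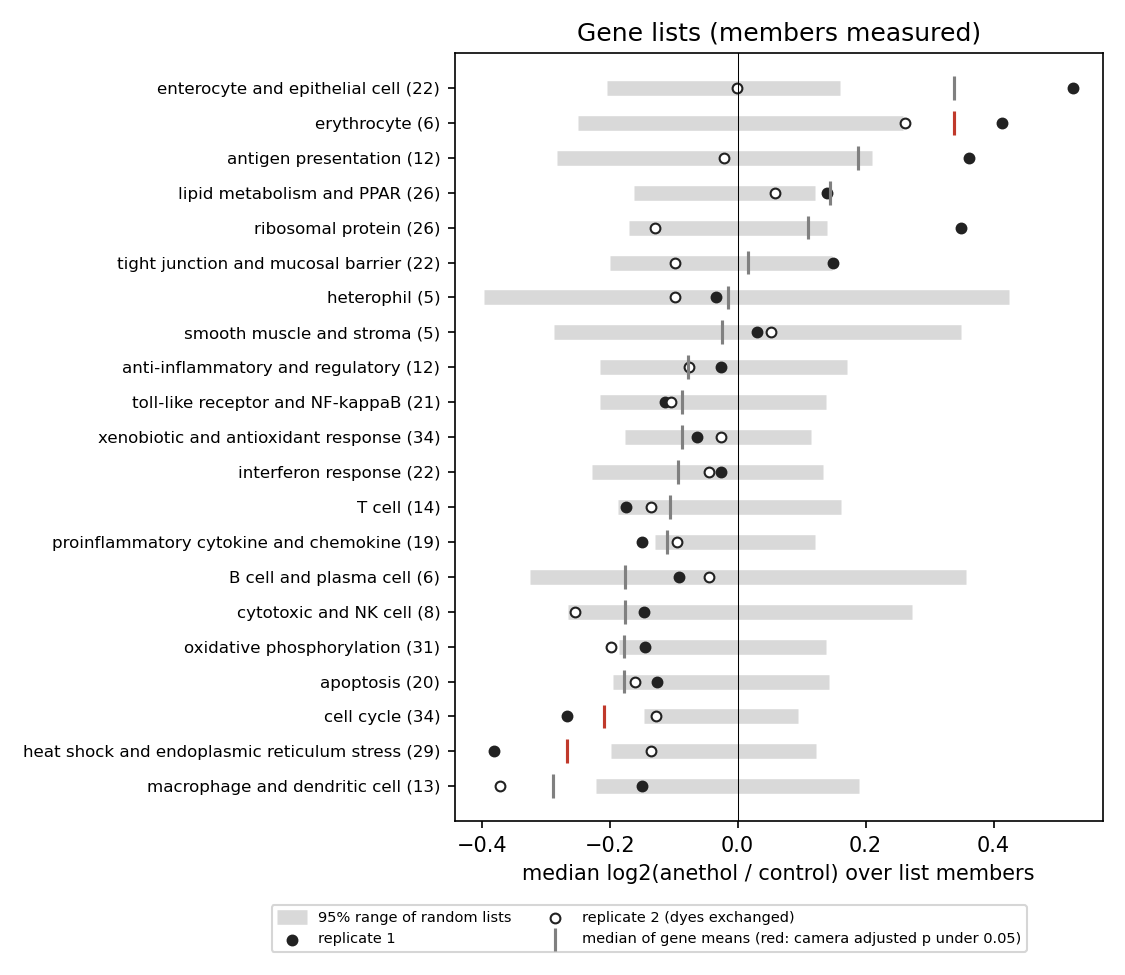
Median log2 ratio of anethol over control for each tested gene list, with the number of measured members in parentheses; filled and open circles are replicates 1 and 2, bars the median of gene means (red where the camera adjusted p was under 0.05), and grey bands the 95% range of 10000 random lists matched on intensity. Cell cycle at -0.21, heat shock at -0.27 and the macrophage and dendritic cell list at -0.29 lie below their bands, the last without passing camera. Erythrocyte at 0.34, lipid metabolism at 0.14 and the enterocyte list at 0.34 lie above theirs, the enterocyte list with replicate 1 at 0.52 and replicate 2 at 0.00.

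The lymphocyte lists did not pass the test, and no member of them passed alone. The 14 measured T cell genes had a median of -0.11 (adjusted p = 0.756), with 7 negative on both arrays and 5 positive on both. CD3E, a chain of the T cell receptor complex, had -0.69 ± 0.01, the cytokine receptor chain gene IL2RG 0.61 ± 0.61, CD247 0.48 ± 0.66 and CD8BP, listed as CD8B on the array, -0.37 ± 0.20. In the cytotoxic and NK cell list, 7 of 8 members were negative on both arrays (median -0.18, adjusted p = 0.181), led by the death ligand gene TNFSF10 at -0.60 ± 0.10 and the chemokine gene XCL1 at -0.59 ± 0.12, with CD244 at -0.29 ± 0.19 and IL12RB2 at -0.20 ± 0.02. The 6 B cell and plasma cell genes had a median of -0.18 (adjusted p = 0.604), with TNFSF13B at -0.26 ± 0.09 and CD79B at 0.26 ± 0.30. The list of macrophage and dendritic cell genes had the lowest median, -0.29 over 13 members (adjusted p = 0.112), with the activation marker CD83 at -0.76 ± 0.21, LY86 at -0.65 ± 0.31, the protease gene LGMN at -0.65 ± 0.30 and CTSB at 0.67 ± 0.83. Of the 5 heterophil genes, LYG2, a lysozyme of the goose type, had -1.47 ± 0.02 and was the 1 member that passed when adjusted over the list alone, while LYZ had -0.36 ± 0.46 (list median -0.01, adjusted p = 0.277). Only 2 thrombocyte genes were measured, so that list was not tested; its median was 0.04, with the other sign in 3 of the processing alternatives. RAP1B had -0.33 ± 0.09.

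Inflammatory and innate immune lists likewise missed the test. The proinflammatory cytokine and chemokine list had a median of -0.11 over 19 members (adjusted p = 0.181), 12 of them negative on both arrays. The chemokine gene CCL20 had -0.81 ± 0.15, the lymphocyte growth factor gene IL15 -0.77 ± 0.84, and CCL4, listed as K203 on the array, 1.16 ± 1.55, a mean set by replicate 2 (2.25 against 0.06 on replicate 1), with its control channel above background on 1 array. Anti-inflammatory and regulatory genes had a median of -0.08 over 12 members (adjusted p = 0.759). SOCS3, the feedback inhibitor of cytokine signalling, had -0.93 ± 0.11 and was the 1 member past the threshold when adjusted over the list alone, and IL10RA had 1.25 ± 1.27, again set by replicate 2 (2.15 against 0.35), with its control channel above background on 1 array. IL10RB had -0.32 ± 0.06 and SOCS2 0.30 ± 0.10, which turned negative under median centring without loess. Of 21 toll-like receptor and NF-kappaB genes (median -0.09, adjusted p = 0.549), RIPK1 had -0.68 ± 0.64, TRAF5 -0.65 ± 0.17, TOLLIP -0.57 ± 0.54 and NLRX1 0.47 ± 0.33; a second NLRX1 probe had the opposite sign. The 22 interferon response genes had a median of -0.09 (adjusted p = 0.774), with the antiviral genes OASL at 0.73 ± 0.75 and IFIH1 at 0.56 ± 0.03, IFITM5 at 0.55 ± 0.06 and LY6E at -0.62 ± 0.05. The other IFIH1 probes had 0.18 ± 0.25 and -0.43 ± 0.44, the latter negative on both arrays. Of the 12 antigen presentation genes, 4 passed when adjusted over the list alone: B2M, the light chain of MHC class I, at 1.09 ± 0.70, the class II chaperone gene DMB2 at 0.91 ± 0.55, and CD83 and LGMN with the values given above. IFI30, at 0.79 ± 0.90, did not (list median 0.19, adjusted p = 0.323; the median was negative under median centring without loess).

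The cytokine and surface marker genes fixed by name were mostly too dim to compare. Of 18 such genes, 17 were on the array under that name and 8 were tested. IL1B, IL6, IL10, IL13, IL4, IL12B, IFNG and IL2 were not well above background in either channel of either array, and IL8L2 was so on 1 array only. GNLY was not among the probes' gene names. Of the tested genes, 0 passed. IL17A had -0.27 ± 0.20, IL18 0.37 ± 0.86, LITAF -0.08 ± 0.09, TNFSF15 -0.41 ± 0.45, CD8A -0.04 ± 0.14 and NOS2 -0.11 ± 0.12. IL17A, LITAF and CD8A were above background in each RNA's channel on 1 array only, so their ratios lie near the floor. CD4 was not well above background in the anethol channel on either array and so has only a bound there, 1.21-fold lower. That bound carries no error term. The fitted ratio was -0.32 ± 0.04 and missed the limma test (adjusted p = 0.377), so a fall of CD4 is not established.

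Epithelial and stromal lists showed how far the arrays could differ. The 22 enterocyte and epithelial cell genes had a median of 0.34, but 0.52 on replicate 1 and 0.00 on replicate 2, and missed the test at an adjusted p of 0.0559. It passed without a filter on dim probes (adjusted p = 0.0485) and with the mean of all probes of a gene (adjusted p = 0.0276). Under median centring without loess its median was -0.11, where the median of all tested probes was -0.19. CUBN, an endocytic receptor, had 0.71 ± 0.06, while the intestinal transcription factor genes CDX2 at 0.76 ± 1.05 and HNF4A at 0.66 ± 0.84 and the disaccharidase gene MGAM at 0.59 ± 0.72 were close to 0 on replicate 2. Of the 22 tight junction and mucosal barrier genes (median 0.02, adjusted p = 0.819; negative under median centring without loess and after scaling to one spread), 2 passed when adjusted over the list alone, FCGBP and CLDN10. FCGBP, a mucus protein, had 1.91 ± 1.14 and was positive with all 4 of its probes, CLDN10, a claudin, had -1.87 ± 0.32 (adjusted p = 0.0584), the desmosome gene DSP 0.69 ± 0.37 and TJP1 0.59 ± 0.06. The 5 smooth muscle and stroma genes had a median of -0.02 with a mean of 0.17 and an upward test direction (adjusted p = 0.604), and the median turned positive in 3 of the processing alternatives. VCL had 0.71 ± 0.96, with its control channel above background on 1 array, the endothelial gene PECAM1 0.63 ± 0.18 (0.13 ± 0.33 with its other probe, with opposite signs on the arrays) and ACTG2 -0.33 ± 0.09.

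Metabolic lists also missed the test. Of the 34 xenobiotic and antioxidant response genes (median -0.09, adjusted p = 0.323), 4 passed when adjusted over the list alone, among them GSTT1, GSTA3 and CYP1A2. The glutathione transferase genes GSTT1 and GSTA3 had -1.21 ± 0.07 and -0.99 ± 0.01, and CYP1A2, a cytochrome P450 of the aryl hydrocarbon response listed as CYP1A1 on the array, had 1.28 ± 0.50 (0.70 ± 0.08 with its other probe). The peroxiredoxin gene PRDX6, at 0.84 ± 0.73, did not pass. Lipid metabolism and PPAR genes had a median of 0.14 over 26 members (adjusted p = 0.277; negative under median centring without loess), with the lipid droplet gene PLIN2 at 0.99 ± 0.92, the sterol regulator gene INSIG1 at 0.93 ± 0.58 and ACAT1 at -0.83 ± 0.29. The 26 ribosomal protein genes had a median of 0.11, with 0.35 on replicate 1 and -0.13 on replicate 2 (adjusted p = 0.277; negative under median centring without loess). RPL7A had 1.69 ± 0.00, with its control channel above background on 1 array, RPL39L 1.11 ± 0.19 and RPLP2 0.83 ± 0.00, and these 3 passed when adjusted over the list alone. RPL3 had 0.75 ± 0.91. Oxidative phosphorylation genes had a median of -0.18 over 31 members (adjusted p = 0.277), with NDUFA10 at -0.91 ± 0.46, ATP5PB at -0.80 ± 0.41, NDUFB4 at -0.69 ± 0.06 and NDUFA5 at -0.65 ± 0.63. The 20 apoptosis genes had a median of -0.18 (adjusted p = 0.102), 10 of them negative on both arrays and 0 positive on both, with CASP8 at -0.49 ± 0.28, BIRC2 at -0.46 ± 0.32 and CASP6 at -0.45 ± 0.24.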

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

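The counts, but not the direction of the named genes, depended on the processing. In each of the 8 processing alternatives in which they were measured, all 11 named genes past the test kept their sign, as did the other named genes except SOCS2 under median centring; the 11 genes passed in 2 to 4 of them. Of the 28 probes past the test, the count rose to 1929 with an offset of 16 (1595 higher, 334 lower) and to 1771 with an intensity trend in the variance model (1478 and 293), and each of these included all 28. It was 221 with only probes above background in both channels on both arrays (175 and 46), 14 after median centring without loess, 1 after scaling the log ratios to one spread, and 0 with the scanner software's processed signals, 0 with the series table and 0 without a filter on dim probes, where 2536, 2536 and 4423 probes had an unadjusted p under 0.05. It was 0 in the dye direction. Leaving out the probes of 17 named exocrine pancreas genes, an alternative chosen after seeing the data, left 5 (1 higher, 4 lower), fewer partly because fewer small p-values enter the adjustment.

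Of 246 probes at least 2-fold apart on both arrays, the count was 441 with an offset of 16, 1191 with the scanner's processed signals and 1191 with the series table (780 higher, 411 lower), 73 after median centring and 931 at 1.5-fold. It was 0 in the dye direction. On a single array it was 483 to 1514. In the dye direction an offset of 16 gave 12 probes, the scanner's signals 309 and median centring 1193. The Pearson r of the arrays fell from 0.55 to 0.0465 after median centring, where the median of all tested probes was -0.19, and to 0.43 without a filter on dim probes, which takes in spots at background.

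Of the 3 gene lists past the test, 0 were called with an estimated correlation (smallest adjusted p 0.781), 1 without background subtraction and 0 with the stricter filter. fry, which tests whether genes of a list move one way, called 2 others, cytotoxic and NK cell and anti-inflammatory and regulatory, at an adjusted p of 0.0236 each. Except where a construction is named, the cause was not tested. Signal over background limits what can be seen here: the median spot was 57.6 in Cy3 and 64.1 in Cy5 on replicate 1, over local backgrounds of 43 and 53.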

Other observations

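Apart from the pancreatic enzymes, the lower genes that were at least 2-fold apart on both arrays included the insulin gene INS at -1.22 ± 0.10 (SD, n = 2), the fibrinogen chain gene FGG at -1.38 ± 0.38 and the intestinal homeobox gene ISX at -1.27 ± 0.16. On the higher side were the corticotropin-releasing hormone gene CRH at 1.73 ± 0.02, the transcription factor gene PHOX2 at 1.53 ± 0.14, the fast muscle troponin gene TNNT3 at 1.45 ± 0.11 and OLIG2 at 1.18 ± 0.13. IAPP, the islet amyloid peptide that beta cells release with insulin, had 1.37 on replicate 1 and 1.02 on replicate 2, opposite to INS. None of these passed the limma test (adjusted p of 0.0513 for CRH and more for the others), and all were chosen after their values were seen. INS and FGG were above background in the anethol channel on 1 of 2 arrays, and CRH, PHOX2 and OLIG2 in the control channel on 1 of 2, so the exact ratios are uncertain. Probes of 1 gene differed in size: the brightest APOB probe had 0.44 ± 0.12 and the dimmest 1.95 ± 0.62, all 4 being positive.

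A probe annotated as an MHC B-G antigen clone, without a gene name here, passed as higher at 1.89 ± 0.00 (adjusted p = 0.0403). The array's coordinates place it on chromosome 14 from 13962357 to 13962416, between the HBZ probe that starts at 13958638 and the HBA1 probe that starts at 13965132. Among the probes past the test, an unnamed clone with a ratio of 2.37 ± 0.25 lies 67.8 kb from GDF2 on chromosome 6. On the unplaced sequence, another, at -4.54 ± 0.01, lies 538 bases from CTRC. On replicate 2 alone, 91 probes were at least 2-fold higher while within 0.25 of 0 on replicate 1, and 3 were at least 2-fold lower; on replicate 1 alone the counts were 348 and 110.

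All the patterns below were picked after the results were seen, and the tests of dye bias were also written after: the lower pancreatic enzyme transcripts may come from pancreatic tissue carried along in the control RNA, since the pancreas lies in the duodenal loop and intraepithelial lymphocytes do not normally make these enzymes. All 13 listed genes seen beforehand were lower on both arrays (median -3.37), which excludes dye bias as their sole cause, because the dyes were exchanged. Genes not looked at before listing left the carry-over open. The 4 measured genes of the exocrine list had a median of -0.30, with CUZD1 at -0.49, RBPJL at -0.45, AMY1A at -0.14 and SPINK5, better known from epithelia, at 0.80. With or without SPINK5 this is short of the bound set for it. RBPJL was above background in the anethol channel on 0 arrays and AMY1A on 1, with control log2 intensities of only 6.61 and 6.31. Ratios this near the floor could hardly reach the bound, so falling short of it says little. The 6 islet genes had a median of 0.13, from the hormone gene GCG at -0.92, lower on both arrays like INS above, to NKX2-2 at 1.09. That islet median, 0.18 on replicate 1 and 0.09 on replicate 2, meets the bound written beforehand for counting against carry-over (above 0), and it is left open only by a condition on spread added after the values were seen. An effect of anethol on these transcripts within the gut stays open as well and was not tested.

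Picked after the result was seen, and with the tests of noise and of other filters chosen after: more probes were at least 2-fold higher than lower, 205 against 41. A spatial artefact shared by the arrays was argued against by the neighbouring spots, whose mean ratio had a median of 0.0177 at most. Noise of dim probes was argued against as the whole cause by the 0 probes that were 2-fold in the same dye direction. Independent noise would put as many there as in the treatment direction. The offset of 50 draws dim probes towards 0, however. An offset of 16 put 12 probes in the same dye direction, and the scanner's processed signals put 309 there. Left open is a wider rise of transcripts of other tissues or of unspecific signal in the anethol channel: the median of 18 genes of nerve, muscle, eye, liver and embryo, 0.26, lay at percentile 99.98 of random lists matched on intensity, but at 96.2 (10 genes, median 0.17) among genes above background in both channels and at 72.0 (74 genes, median 0.00) without a filter, so the filter on dim probes shaped it. The asymmetry was absent after median centring without loess (30 against 43). There the tested probes had medians of 0.27 on replicate 1 and -0.82 on replicate 2, so this count carries a common shift and does not decide the question. The spike-in ratios pointed towards the anethol channel on at least 1 array. Spike-ins are added RNA and not transcripts of the samples, and their ratios were not set against expected ones, so they do not decide the question either.

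Picked after the result was seen, with the dye bias test written after: the higher globin transcripts may reflect more red blood cells in the anethol RNA. Dye bias as the sole cause was argued against, as both tested globin probes, 2 in number, were higher on both arrays. They had been picked with that already seen. HBA1, at 4.01 on replicate 1 and 1.66 on replicate 2, leaves room for a part played by the dyes. The 5 erythroid genes not looked at before listing had a median of 0.0840, with 0.18 on replicate 1 and -0.03 on replicate 2. All but BPGM were above background in the control channel on 1 array only. Their control log2 intensities ran from 6.04 for SLC25A37 to 6.30 for TSPO2, so their ratios lie near the floor. These genes therefore do not decide whether red blood cells or an effect of anethol lie behind the globins.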
